A study of Sus scrofa with 47 samples.

How the data were processed

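Mucosa of the jejunum, ileum and colon was taken from 16 crossbred piglets of both sexes, about 4 weeks old. Some were given Salmonella enterica serovar Typhimurium phage type DT104 by mouth and necropsied 1, 2 or 6 days post infection (dpi); the non-infected pigs were necropsied 2 h before the others were infected. Per the labels' protocols, total RNA was purified with a column kit, and biotin-labelled cRNA was prepared by the Affymetrix protocol and measured on porcine GeneChip arrays. There were 47 arrays in 12 groups, with 4 arrays in each group except ileum at 1 dpi, which had 3. Within a tissue each array came from another pig, so the spread between arrays of a group is a spread between animals.

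The values used are the deposited log2 expression values per probe set, which were made by robust multi-array averaging (RMA) with R 2.7.0, per the submitters' processing notes. RMA subtracts a background, forces the arrays normalised together to 1 distribution, and summarises the probes of a set. The sorted values of arrays of 1 tissue lay close to each other (median distance 0.0488 log2), and those of arrays of different tissues did not (0.127), as they would had the tissues been normalised apart, which the notes do not state; tissues that differ in their profiles could also give this. The median log2 value of an array was 6.47 to 6.57 in jejunum, 6.49 to 6.57 in ileum and 6.65 to 6.72 in colon. Levels of different tissues were therefore not compared, except to check 1 array that resembles another tissue, and the planned test among the tissues of non-infected pigs was not run. Changes within a tissue were compared between tissues. The fixed distribution also means that a change of the whole RNA output of a tissue could not be seen. An array gives no count of molecules, so the number of arrays limits the precision.

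Of 24123 probe sets, 124 controls were left out and 23999 were tested. The annotation supplied for the array pairs 10069 of the tested probe sets with 1 gene symbol, 198 with several and 13732 with none; only those with 1 symbol were named. A gene was represented by its probe set with the highest mean over all arrays, which gave 6765 genes, and another probe set of the gene that changed the opposite way is mentioned. By their Entrez numbers, 6694 of these genes were found in the pig RefSeq table of assembly Sscrofa11.1, and 0 had another symbol there. No genome sequence was used here, and no coordinates are given.

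Each tissue was fitted on its own with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 4 groups and the default empirical Bayes step. Each day was compared with the non-infected pigs in 9 two-sided comparisons, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. A moderated F test over the infected groups asked whether the days differed. A fit of all 47 arrays, with an F test on the interaction contrasts, asked whether the change from non-infected pigs differed among the 3 tissues. All adjusted p values of genes in the text are from these limma fits, and errors of changes (±) are standard errors unless SD is written. The 27 gene lists covered cytokines and antimicrobial defence, absorptive and secretory functions of the epithelium, immune and stromal cell types, stress and metabolism. Some genes are in more than 1 list: LTB is in those of cytokines and of B cells, and S100A9 in those of neutrophils and of antimicrobial proteins. Results of lists that share genes are therefore not separate evidence. Each list was tested with camera, in limma, at a preset correlation of 0.01, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. For each list the members at an adjusted p under 0.05 were counted, over all probe sets and adjusted over the list alone.

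Genes were named by a rule. In each comparison the rule takes the 8 largest rises and the 8 largest falls among called genes whose infected and non-infected arrays do not overlap, the 4 members of each list with the smallest p, and any called member of the lists on bile acids, cytokines, and ion and water transport. For the F tests it takes the 6 genes with the smallest p and members of the lists. The groups, the comparisons, the tests, the gene lists, the rule and most alternatives were fixed before the data were examined. The alternatives changed the normalization, the filter on dim probe sets, the empirical Bayes step, the array weights, the arrays in the fit, the unit tested and the list test, added the replicate number as a block, or left out each array in turn. Others were chosen after seeing the data: a fit without a pair of arrays labelled jejunum non-infected, an RNA integrity score and a smooth muscle score as covariates, the tissue test without 1 array, a joint quantile normalization of jejunum and colon to check that array, and splits of whole pigs for the tissue test. The RNA integrity score is the 3′ minus the 5′ control probe sets, averaged over GAPDH and actin; a higher score goes with RNA that is more degraded or less completely transcribed. List scores per array are means over the list, compared with exact two-sided permutation tests.

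The same replicate numbers occur in each tissue, and the labels do not say whether a number means 1 pig. This was checked with 32 probe sets that vary like alleles, chosen on the ileum and colon arrays alone (correlation above 0.9 between both tissues, range over 1.5 log2). Of the 15 jejunum arrays that could be matched, 15 correlated best with the pig of their own day and number, where 1 would by chance. With 18 probe sets chosen at a correlation above 0.95, 13 of the 15 did. The deviations from the group means of same-numbered arrays had a median correlation of 0.24 over 46 pairs of tissues (−0.12 to 0.47), above 0.1 in 37. The numbers thus mark 1 pig across tissues, as read from the data, and the tests among tissues are given also with the pig as a random block. Within a tissue the same number marks different animals, necropsied on different days, and is not taken as a pairing.

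The steps were tested on simulated values of 23999 probe sets with 67, 67 and 66 changed by 1.5-, 2- and 4-fold. Of changes of 2-fold, 59.7% were recovered in the simulation of jejunum at 2 dpi, 83.6% in that of ileum at 1 dpi and 88.1% in that of ileum at 6 dpi; of changes of 4-fold the shares were 95.5%, 95.5% and 100%. Wrong calls were 1.90% to 7.09% of calls over the 9 comparisons. The list of enterocyte genes, shifted by −0.5 log2, was found in the simulations of ileum (camera adjusted p = 5.1e-09) and colon (5.0e-32). It was missed in that of jejunum (0.142), and 0 of 81 list tests without a shift passed in each. The mean of this list had an SD of 2.19 in non-infected jejunum, which holds the array that resembles another tissue, and 0.19 in non-infected colon. Only this list was shifted, so the power for other lists was not measured. The simulated noise was independent between probe sets. These list results therefore do not show how often camera passes lists whose genes vary together, as genes of real arrays can. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.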

Results

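The arrays followed the mucosa of 3 intestinal sections, jejunum, ileum and colon, through an oral infection of piglets with Salmonella Typhimurium. Each section was measured in non-infected pigs and at 1, 2 and 6 dpi, with 4 arrays per group and 3 in ileum at 1 dpi. The question, as the labels state it, is how the mucosal response develops over time and differs along the gut. Changes are differences of mean log2 expression between infected and non-infected pigs, so that a change of 1 is a doubling, and ± gives the standard error. The genes with the largest changes are those whose infected and non-infected arrays did not overlap. An array carries no count of molecules, so the number of pigs limits the precision.

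Of the 47 arrays, 46 had their highest median correlation with arrays of their own section. The array labelled jejunum non-infected replicate 1 correlated with colon arrays at a median of 0.975 and with jejunum arrays at 0.947. Its level of FABP2, a fatty acid-binding protein of small-intestinal absorptive cells, was 3.66 log2, against 9.96 to 13.6 in the other 15 jejunum arrays. It was kept under its label, and values without it stand beside most of the jejunum counts and some of the genes. No pair of arrays was a duplicate, and the highest correlation of a pair was 0.993. EIF1AY, a Y-linked gene, was high in some pigs and low in others, as sex would give. In jejunum replicates 1 to 4 it was 2.97, 2.86, 2.81 and 9.48 in non-infected pigs and 9.06, 3.15, 8.55 and 9.47 at 2 dpi. It was 2.65, 3.05, 9.16 and 9.15 at 1 dpi and 3.02, 9.27, 9.53 and 2.77 at 6 dpi. Sex was thus partly confounded with infection, and no fit adjusted for it. Ileum non-infected replicate 2 lay between, at 5.47, while the arrays of the same pig number were at 2.86 in jejunum and 3.46 in colon. The middle value was thus found in its ileum array alone, and its cause was not tested. Ileum counts at 1 and 6 dpi without this array are given below.

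**Figure D1:**
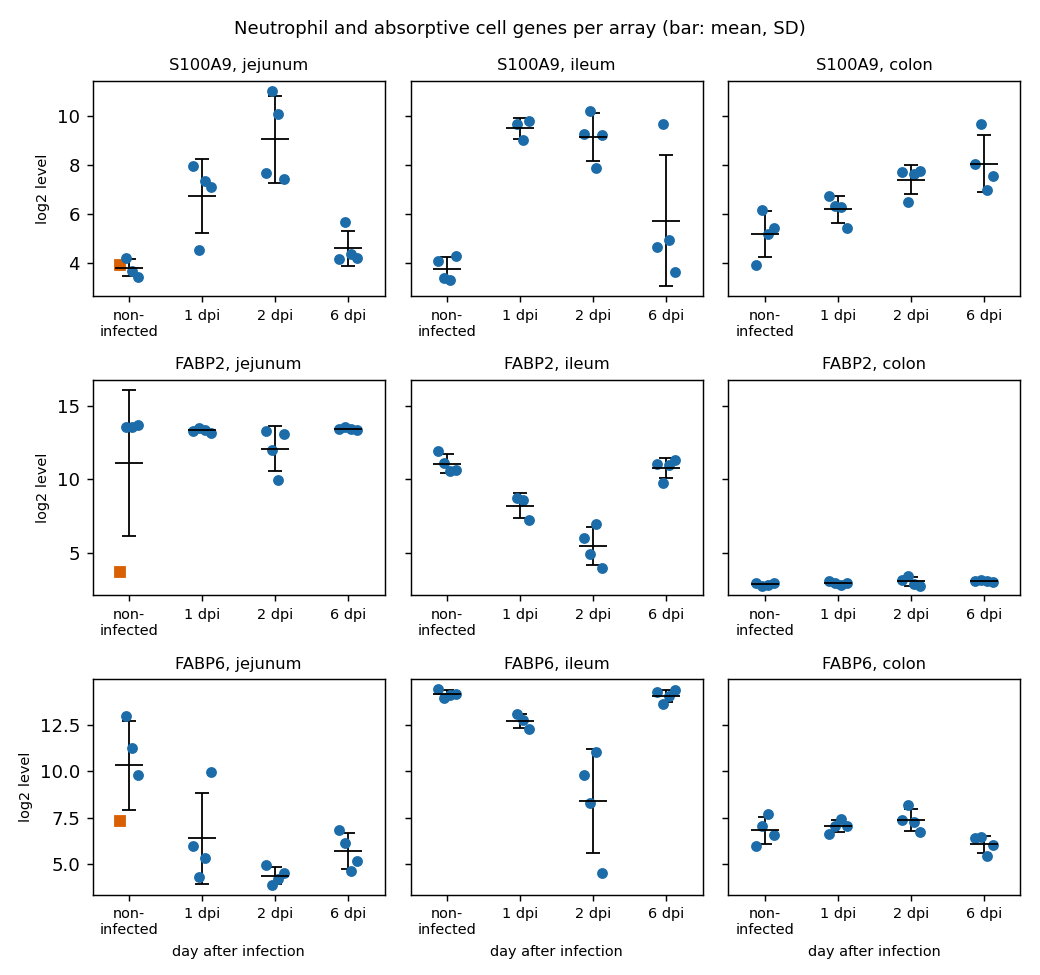
Log2 expression of S100A9, FABP2 and FABP6 in each array (points) of jejunum, ileum and colon by group, with the group mean and SD; the orange square is the array labelled jejunum non-infected replicate 1. In ileum, FABP2 fell by 5.61 and FABP6 by 5.75 at 2 dpi while S100A9 rose by 5.39.

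In ileum at 1 dpi, genes of the absorptive epithelium fell and genes of acute inflammation rose. S100A9, a calcium-binding protein abundant in neutrophils, rose by 5.75 ± 0.99 (adjusted p = 0.0041). CXCL2 and CXCL8, which attract neutrophils, rose by 3.72 ± 0.52 and 2.78 ± 0.40. SLC5A1, the sodium-glucose cotransporter, changed by −3.53 ± 0.46 (adjusted p = 0.00064), and the apolipoproteins APOA1 and APOB, which package dietary fat, by −3.94 ± 0.69 and −3.90 ± 0.67. In all, 624 probe sets rose and 804 fell, of which 202 and 237 changed at least 2-fold.

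Of the 29 measured genes for the enterocyte brush border and nutrient absorption, 20 fell and 0 rose (26 fell and 2 rose adjusted over the list alone; camera adjusted p = 3.0e-14, adjusted p = 0.200 with an estimated correlation). Their median change was −2.05. AMN, the anchor of the vitamin B12 receptor, changed by −3.38, and the peptidases DPEP1 and MEP1B by −3.77 ± 0.44 and −3.84 ± 0.77. Of 22 genes for ion and water transport 10 fell (11 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.0034, adjusted p = 0.361 with an estimated correlation). The water channels AQP8 and AQP3 changed by −4.78 ± 0.79 and −2.33 ± 0.31, and SLC26A3, which exchanges chloride for bicarbonate, by −1.57. Of 12 genes for bile acid transport and signalling 3 fell and 1 rose (6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0105, adjusted p = 0.264 with an estimated correlation). The efflux pumps ABCG2 and ABCB1 changed by −3.03 ± 0.32 and −1.79 ± 0.25, and SULT2A1, which sulfates bile acids and steroids, rose by 1.66 ± 0.19 (adjusted p = 0.00029).

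Of 30 inflammatory cytokines and chemokines measured in ileum at 1 dpi, 12 rose and 0 fell (13 rose adjusted over the list alone; camera adjusted p = 3.6e-09, adjusted p = 0.200 with an estimated correlation). They included CCL2, which attracts monocytes (2.00 ± 0.32), IL1B (2.85 ± 0.56), IL6 (1.28) and IL12B, a subunit of IL-12 and IL-23 (0.95 ± 0.11). The probe set that stands for AMCF-II, a pig neutrophil chemokine, gave 0.09 and was not called, whereas another probe set of the gene rose by 3.27 ± 0.43. Of 25 antimicrobial and acute phase proteins 7 rose (11 adjusted over the list alone; camera adjusted p = 9.3e-06, adjusted p = 0.0703 with an estimated correlation). Of 17 endoplasmic reticulum stress genes 10 rose (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 3.3e-09, adjusted p = 0.0703 with an estimated correlation), among them the chaperones HYOU1 (1.23) and MANF (1.20). DUOX2, which makes hydrogen peroxide at the epithelial surface, rose by 2.86 ± 0.45, the mitochondrial superoxide dismutase SOD2 by 1.97 ± 0.28 and the prostaglandin synthase PTGS2 by 2.13 ± 0.39. Interferon-stimulated genes went both ways, with 6 of 31 higher and 7 lower (9 and 14 adjusted over the list alone; camera adjusted p = 0.219). SAMHD1 and WARS rose by 1.45 and 1.91, while MX1 and IFIT3, both antiviral effectors, changed by −1.65 and −1.59.

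Of 70 genes named by the rule in ileum at 1 dpi, 41 stayed called without any 1 array. The calls of IL1B and APOC3 (−3.74 ± 0.74) were lost without 1 dpi replicate 4, where the changes were 2.67 and −3.13. Without that array 427 probe sets were called in place of 1428, and without non-infected replicate 2 it was 802. Without 1 dpi replicate 4, 10 enterocyte genes and 3 transport genes fell, 6 cytokines and 2 antimicrobial proteins rose and 0 interferon-stimulated genes fell over all probe sets by limma (21 of the list at an unadjusted p under 0.05), while camera passed each of the first 4 lists. Ion and water transport had 6 fallen without non-infected replicate 2 and 5 without 1 dpi replicate 2, and antimicrobial proteins 4 risen without non-infected replicate 2 or 1 dpi replicate 3. The interferon-stimulated genes that fell were 3, 14 and 1 without non-infected replicates 2, 3 and 4 and 2 without 1 dpi replicate 3, and their list passed camera as lower without non-infected replicate 3 (adjusted p = 0.0016).

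In ileum at 2 dpi the loss of absorptive transcripts was the main feature. FABP2 changed by −5.61 ± 0.55 (adjusted p = 6.8e-05), FABP6, the ileal bile acid-binding protein, by −5.75 ± 0.90 (adjusted p = 0.0021), the retinol-binding protein RBP2 by −5.45 ± 0.59 and SLC5A1 by −4.51 ± 0.42. S100A9 rose by 5.39 ± 0.92, the haemoglobin scavenger receptor CD163 of macrophages by 3.01 ± 0.54, and MUC4, a membrane mucin, by 2.84 ± 0.55. In all, 658 probe sets rose and 574 fell, of which 147 and 243 changed at least 2-fold.

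Of the 29 enterocyte genes, 23 fell and 1 rose (26 and 2 adjusted over the list alone; camera adjusted p = 6.9e-24, adjusted p = 0.170 with an estimated correlation), with a median of −2.21. Of 22 ion and water transport genes 9 fell (11 adjusted over the list alone; camera adjusted p = 1.3e-05, adjusted p = 0.237 with an estimated correlation), among them SLC26A3 (−2.60 ± 0.27), AQP3 (−2.68 ± 0.29) and GUCA2B, the precursor of uroguanylin (−1.81). Of 12 bile acid genes 3 fell (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00054, adjusted p = 0.170 with an estimated correlation). Of 29 xenobiotic metabolism genes 6 fell (7 adjusted over the list alone; camera adjusted p = 0.00027, adjusted p = 0.170 with an estimated correlation), including the esterase CES1 (−2.26 ± 0.29) and the sulfotransferase SULT1E1 (−4.09 ± 0.64). Of 30 cytokines 7 rose (16 adjusted over the list alone; camera adjusted p = 8.8e-07, adjusted p = 0.245 with an estimated correlation), with CXCL2 at 2.64 ± 0.48 and CCL2 at 1.93. Of 17 complement genes 6 rose (10 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00022, adjusted p = 0.260 with an estimated correlation), with C3 at 0.48. The epithelial defensin DEFB1 rose by 2.22 ± 0.35 and CHI3L1, a secreted chitinase-like protein, by 2.35 ± 0.34. Interferon-stimulated genes again went both ways, with 6 of 31 higher and 9 lower (8 and 17 adjusted over the list alone; camera adjusted p = 0.0179, adjusted p = 0.522 with an estimated correlation). Camera no longer passed without non-infected replicate 1 (adjusted p = 0.181). The interferon-stimulated genes that rose were 3 and 2 without non-infected replicates 2 and 4, and 3, 2 and 2 without 2 dpi replicates 1, 2 and 4; those that fell were 14 and 2 without non-infected replicates 3 and 4, and 5, 3 and 2 without 2 dpi replicates 1, 2 and 4. The cytokine count was 4 without non-infected replicate 2 (9 adjusted over the list alone) or 2 dpi replicate 1 or 4, and 3 without 2 dpi replicate 2. The complement count was 3 without non-infected replicate 2 or 3, and 2 without non-infected replicate 4 or 2 dpi replicate 1, 2 or 4. The xenobiotic count was 3 and 2 without 2 dpi replicates 2 and 4. MX1 changed by −1.74 ± 0.36 and SAMHD1 by 1.55.

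Of 67 named genes in ileum at 2 dpi, 42 stayed called without any 1 array, among them FABP2, FABP6, RBP2, SLC5A1, S100A9, CD163 and MX1. The count of 1232 probe sets fell to 668 without non-infected replicate 4, and to 759, 595 and 623 without 2 dpi replicates 1, 2 and 4. With the RNA integrity score as a covariate, added after seeing the data, it was 513. The median size of the change of the 1232 was then 0.736 in place of 0.797, with a median standard error of 0.184 in place of 0.173, and 1232 kept their sign.

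At 6 dpi the ileum no longer differed in its absorptive genes by this test and showed a broad set of smaller changes. FABP2 was at −0.31 (adjusted p = 0.74), and of the 29 enterocyte genes 0 were called by limma, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.419, fry 0.637). The macrophage receptors CD163 and FCGR3A rose by 2.46 ± 0.54 and 1.63, and the matrix-degrading enzymes MMP1 and MMP3 by 2.61 ± 0.49 and 2.57 ± 0.52. CD79B, a part of the B cell receptor, changed by −1.37 ± 0.21 (adjusted p = 0.00091), and SPIB, a transcription factor of B cells, by −1.23 ± 0.21. In all, 2421 probe sets rose and 2298 fell, of which 467 and 214 changed at least 2-fold.

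Of 20 macrophage and monocyte markers 10 rose (15 adjusted over the list alone; camera adjusted p = 1.2e-05, adjusted p = 0.444 with an estimated correlation), with a median of 0.98. The macrophage list mean of 6 dpi replicate 2 was 9.66, against 8.30 to 8.55 in the other 3, and without that array the median change was 0.52, with 9 called and 10 adjusted over the list alone. Of 15 genes for antigen presentation on MHC class II 8 rose (8 adjusted over the list alone; camera adjusted p = 0.00031, adjusted p = 0.444 with an estimated correlation), with SLA-DRB1 at 1.21 ± 0.19. Of 26 fibroblast and matrix genes 12 rose (15 adjusted over the list alone; camera adjusted p = 2.9e-06, adjusted p = 0.444 with an estimated correlation), such as periostin, POSTN (2.17 ± 0.43), and lumican, LUM (1.71). Of 18 smooth muscle markers 9 rose (10 adjusted over the list alone; camera adjusted p = 1.2e-05, adjusted p = 0.444 with an estimated correlation), with ACTA2 at 1.25 ± 0.17. Of 6 B cell markers 5 fell (5 adjusted over the list alone; camera adjusted p = 0.00037, adjusted p = 0.444 with an estimated correlation), while 3 of 8 plasma cell markers rose (6 adjusted over the list alone; camera adjusted p = 0.0015, adjusted p = 0.444 with an estimated correlation), with TNFRSF17 at 0.80 and XBP1 at 0.67. Of 27 cell cycle genes 15 fell (17 fell and 2 rose adjusted over the list alone; camera adjusted p = 3.2e-06, adjusted p = 0.444 with an estimated correlation), with the replication factors MCM2 at −0.88 and MCM3 at −0.74 and the ribonucleotide reductase subunit RRM1 at −0.75 ± 0.12. Of 30 cytokines 8 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.0047, adjusted p = 0.522 with an estimated correlation), with CXCL8 at 2.01 ± 0.37 and the lymphotoxin LTB, which shapes lymphoid tissue, at −0.86. The nuclear receptor NR1I2, a sensor of bile acids and drugs, rose by 1.51 ± 0.22. Of 31 interferon-stimulated genes 6 rose (8 adjusted over the list alone; camera adjusted p = 0.0016, adjusted p = 0.522 with an estimated correlation), a camera call lost without non-infected replicate 3 (adjusted p = 0.0574). That count was 12, 2 and 2 without non-infected replicates 1, 2 and 3, and 2 and 3 without 6 dpi replicates 1 and 3 (15, 1, 1, 2 and 2 adjusted over the list alone). The cell cycle count was 9 without non-infected replicate 2. The plasma cell count was 6 without non-infected replicate 1, and adjusted over the list alone 3 without non-infected replicate 2 or 4. The cytokines that rose were 7 adjusted over the list alone without non-infected replicate 2 or 6 dpi replicate 2; 0 fell by limma without non-infected replicate 2 or 4 (13 of the list at an unadjusted p under 0.05 each), and 1 did without 6 dpi replicate 3 or 4.

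The RNA integrity score moved with this group. It was 0.916 ± 0.102 (SD, n = 4) in ileum at 6 dpi and 1.31 ± 0.15 (SD, n = 4) in non-infected ileum, a difference of −0.398 (exact permutation p = 0.0286, the smallest possible here, and 0.257 adjusted over 9 comparisons). With the score as a covariate, added after seeing the data, limma called 0 probe sets (3230 at an unadjusted p under 0.05). The median size of the change of the called probe sets was then 0.501 in place of 0.608, its median standard error 0.240 in place of 0.146, and 4664 of 4719 kept their sign. Without non-infected replicate 2 the count was 2977. Of 93 named genes 65 stayed called without any 1 array; the call of LTB was lost without non-infected replicate 2 (−0.76) or 4 (−0.70).

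**Figure D2:**
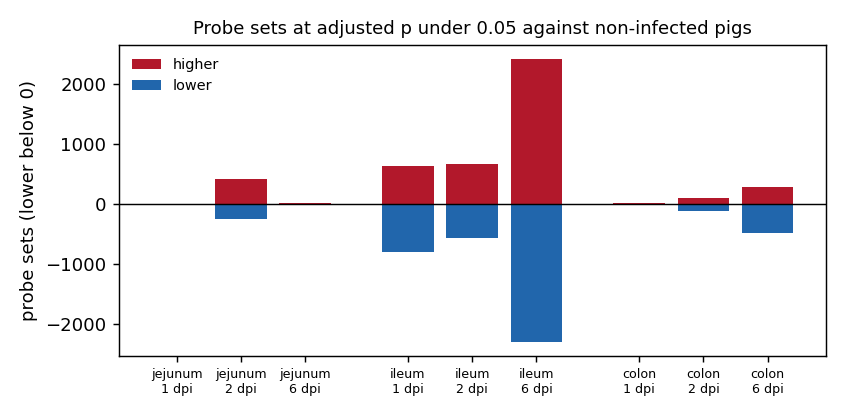
Number of probe sets called higher (up) and lower (down) than in non-infected pigs of the same section at 1, 2 and 6 dpi, one bar per comparison. The counts run from 1 in jejunum at 1 dpi to 4719 in ileum at 6 dpi.

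In jejunum at 1 dpi, 1 probe set was called. It has no gene symbol in the annotation supplied, was looked up after its value was seen, and rose by 5.48 ± 0.51 (adjusted p = 0.00043). Among the lists, 28 of 30 cytokines were higher, with 0 called by limma over all probe sets and 4 higher adjusted over the list alone (camera adjusted p = 2.0e-09, adjusted p = 0.193 with an estimated correlation). Of 17 endoplasmic reticulum stress genes 16 were higher, 8 of them past the threshold adjusted over the list alone (camera adjusted p = 2.5e-08, adjusted p = 0.193 with an estimated correlation), and of 17 complement genes 15 were higher (4 adjusted over the list alone; camera adjusted p = 8.4e-07, adjusted p = 0.193 with an estimated correlation). S100A9 was at 2.93 ± 0.78 (adjusted p = 0.30). These counts adjusted over the list alone became 3, 3 and 2 without the array labelled jejunum non-infected replicate 1. Over each array left out they ran from 1 to 9 for cytokines, 0 to 11 for endoplasmic reticulum stress and 2 to 5 for complement, while camera passed each time. At an unadjusted p under 0.05 there were 2321 probe sets, and the number called was 6 without 1 dpi replicate 1, 2 without 1 dpi replicate 2, and 1 without the array labelled jejunum non-infected replicate 1.

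In jejunum at 2 dpi some inflammatory genes rose and 3 of 22 genes for ion and water transport fell. S100A9 rose by 5.24 ± 0.78 (adjusted p = 0.0048), CXCL2 by 3.59 ± 0.59 and STEAP4, a metalloreductase induced in inflammation, by 2.69 ± 0.39. FABP6 changed by −5.93 ± 1.13 (adjusted p = 0.015) and SLC26A3 by −3.40 ± 0.51. ATP4B, a subunit of the gastric proton pump, rose by 3.67 ± 0.65, and haptoglobin, HP, an acute phase protein, by 2.85 ± 0.58. In all, 420 probe sets rose and 260 fell, of which 150 and 121 changed at least 2-fold. Without the array labelled jejunum non-infected replicate 1, 322 rose and 198 fell, 387 of them shared with the 680. S100A9 was then at 5.28 ± 0.86, FABP6 at −6.94 ± 1.03 and SLC26A3 at −3.06, all still called. In that fit FABP6 was lower at 1 dpi (−4.93, adjusted p = 0.32) and 6 dpi (−5.62, adjusted p = 0.085) too, neither called, so its fall may not be particular to 2 dpi. Its level varied among the non-infected pigs, at 12.97, 11.22 and 9.77 in replicates 2, 3 and 4.

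Of 30 cytokines in jejunum at 2 dpi 3 rose (15 rose and 1 fell adjusted over the list alone; camera adjusted p = 9.5e-06, adjusted p = 0.297 with an estimated correlation). Of 13 neutrophil markers 3 rose (5 adjusted over the list alone; camera adjusted p = 0.0071, adjusted p = 0.330 with an estimated correlation). Of 17 complement genes 5 rose (6 adjusted over the list alone; camera adjusted p = 0.0049, adjusted p = 0.330 with an estimated correlation), among them CFB (1.28 ± 0.21) and C2 (1.34 ± 0.24). The adhesion molecules ICAM1 and SELE, which arrest leukocytes on vessel walls, rose by 1.69 ± 0.28 and 1.59 ± 0.28. Of 22 ion and water transport genes 3 fell (7 adjusted over the list alone; camera adjusted p = 3.9e-06, adjusted p = 0.0543 with an estimated correlation). They were SLC26A3, the bicarbonate transporter SLC4A4 (−1.19 ± 0.23) and AQP8 (−3.41 ± 0.72). AQP8 was no longer called without 2 dpi replicate 2 (−3.15) or 3 (−3.08) or the array labelled jejunum non-infected replicate 1 (−3.001). Complement no longer passed camera without non-infected replicate 2 (adjusted p = 0.0996). Without the array labelled jejunum non-infected replicate 1, 3 cytokines, 2 neutrophil markers and 4 complement genes rose and 2 transport genes fell (11, 5, 5 and 8 adjusted over the list alone). The cytokine count was 1 and 6 without 2 dpi replicates 3 and 4, and adjusted over the list alone 9 without non-infected replicate 2 and 8 without 2 dpi replicate 3. The neutrophil count was 1 without 2 dpi replicate 2 or 3 and 5 without replicate 4. The complement count was 3 without non-infected replicate 3 or 4 and 2 without 2 dpi replicate 2 or 3. The transport count was 1 without 2 dpi replicate 2 or 3 and 5 without replicate 4, and adjusted over the list alone 3 without non-infected replicate 3 or 2 dpi replicate 2 or 3.

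ASNS, which makes asparagine, rose by 2.28 ± 0.26 (adjusted p = 0.0013) and ATF4, the transcription factor of the amino acid and stress response, by 0.88 ± 0.15. Of 17 endoplasmic reticulum stress genes 2 rose in jejunum at 2 dpi (11 adjusted over the list alone; camera adjusted p = 1.2e-07, adjusted p = 0.297 with an estimated correlation). Interferon-stimulated genes went both ways, with 5 of 31 higher and 2 lower (8 and 7 adjusted over the list alone; camera adjusted p = 0.553). SAMHD1 and WARS rose by 1.95 ± 0.35 and 2.19 ± 0.35, while USP18 and MX1 changed by −1.42 ± 0.26 and −1.54 ± 0.33. Of 27 cell cycle genes 1 rose and 26 were higher (11 adjusted over the list alone; camera adjusted p = 1.2e-07, adjusted p = 0.330 with an estimated correlation). Of 34 genes for oxidative phosphorylation 1 fell, NDUFA1 (−0.54 ± 0.13), and 10 did adjusted over the list alone (camera adjusted p = 1.2e-07, adjusted p = 0.337 with an estimated correlation). Another probe set of NDUFA1 was at 2.82, and the mean of its probe sets was higher, so its direction depends on the probe set. Without the array labelled jejunum non-infected replicate 1, 3 endoplasmic reticulum stress genes rose, 3 interferon-stimulated genes rose and 2 fell, and 0 of the cell cycle and oxidative phosphorylation genes were called by limma; adjusted over the list alone the counts were 7, 6 and 7, 4 and 6. The endoplasmic reticulum stress count adjusted over the list alone was 7 without 2 dpi replicate 2 too. The interferon-stimulated genes that rose were 3, 3 and 8 without non-infected replicates 2, 3 and 4, and 3, 2 and 2 without 2 dpi replicates 1, 2 and 3, without each of which 1 fell. Adjusted over the list alone those that fell were 4 without non-infected replicate 2 or 4 or 2 dpi replicate 2, and 12 without 2 dpi replicate 4. Over each array left out in turn, the cell cycle count adjusted over the list alone ran from 0 (without 2 dpi replicate 2 or 3) to 17 (without non-infected replicate 4 or 2 dpi replicate 1), and that of oxidative phosphorylation from 0 (without non-infected replicate 4 or 2 dpi replicate 1 or 3) to 9.

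In jejunum at 2 dpi the lists of smooth muscle and of fibroblasts passed camera as lower, but neither passed fry (adjusted p = 0.0519 and 0.122) or the permutation test of the list means (exact p = 0.143 and 0.286, and 0.214 and 0.367 adjusted over 9 comparisons). Of 18 smooth muscle markers 17 were lower, with 0 called over all probe sets by limma and 10 at an unadjusted p under 0.05 (7 lower adjusted over the list alone; camera adjusted p = 3.9e-06, adjusted p = 0.330 with an estimated correlation), and a median of −0.47. Of 26 fibroblast and matrix genes 1 rose and 2 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.00024, adjusted p = 0.337 with an estimated correlation), with a median of −0.49. The medians were −0.38 and −0.33 without the array labelled jejunum non-infected replicate 1, and camera passed both lists without any 1 array. Without non-infected replicate 2, 5 smooth muscle and 6 fibroblast genes fell (17 and 17 adjusted over the list alone). The smooth muscle count adjusted over the list alone was 0 without non-infected replicate 1, 3 or 4 or 2 dpi replicate 1, 2 or 3, and the fibroblast count was 2 fallen without 2 dpi replicate 1 and 4 without replicate 2. By limma over all probe sets 0 fibroblast genes fell without non-infected replicate 3 or 2 dpi replicate 1, 2 or 3 (13, 12, 16 and 15 at an unadjusted p under 0.05).

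Of 44 named genes in jejunum at 2 dpi, 17 stayed called without any 1 array, among them S100A9, CXCL2, STEAP4, ATP4B, SLC26A3, ASNS, ATF4, CFB, C2, ICAM1, SELE, SAMHD1, WARS and USP18. FABP6 was not called without 2 dpi replicate 3 (−5.87), nor HP without 2 dpi replicate 2 (2.63). The count of 680 became 340 and 389 without non-infected replicates 3 and 4, and 446, 212, 154 and 1028 without 2 dpi replicates 1, 2, 3 and 4.

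At 6 dpi 18 probe sets differed in jejunum, 10 higher and 8 lower. TNFRSF17, the survival receptor of plasma cells, rose by 1.82 ± 0.27 (adjusted p = 0.023), and C4BPB, which restrains complement, by 1.35 ± 0.23. The pancreatic-type amylase AMY2 changed by −1.14 ± 0.15 (adjusted p = 0.012). Of 31 interferon-stimulated genes 30 were higher, with a median of 0.77 and 0 called over all probe sets by limma (15 adjusted over the list alone; camera adjusted p = 3.1e-11, adjusted p = 0.334 with an estimated correlation). IFIT1 was at 2.06 ± 0.41 (adjusted p = 0.067). At an unadjusted p under 0.05 there were 3118 probe sets. Macrophage markers were higher in 18 of 20 cases, with 0 called and 2 past the threshold adjusted over the list alone (camera adjusted p = 8.8e-05, adjusted p = 0.345 with an estimated correlation). Without the array labelled jejunum non-infected replicate 1 the 2 counts adjusted over the list alone were 14 and 2, and the median of the interferon-stimulated genes 0.53. Over each array left out the first ran from 7 to 18 and the second from 0 to 2. Without that array smooth muscle markers also passed camera as lower (median −0.26, adjusted p = 0.00014, 0.450 with an estimated correlation). Cell cycle genes passed as higher (median 0.26, adjusted p = 0.00042, 0.506 with an estimated correlation), and limma called 0 of either list. No gene named here stayed called without each array in turn: AMY2 was lost without 6 dpi replicate 4 (−1.11), TNFRSF17 without non-infected replicate 2 or 4 (1.65, 1.78) or 6 dpi replicate 3 or 4 (1.81, 1.76), and C4BPB without non-infected replicate 1, 3 or 4 (1.37, 1.26, 1.22) or 6 dpi replicate 3 or 4 (1.31, 1.27). The count was 9, 4 and 6 without the non-infected arrays 1, 2 and 4, and 10, 109, 3 and 3 without 6 dpi replicates 1, 2, 3 and 4.

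In colon at 1 dpi few probe sets were called, and 5 of the 6 genes named by the rule encode chaperones or co-chaperones, which were not tested as a group. HSPH1, HSP90AA1 and HSP90B1, which are protein-folding chaperones, rose by 1.46 ± 0.23, 0.68 ± 0.10 and 0.69 ± 0.11, and the co-chaperones STIP1 and SUGT1 by 0.78 ± 0.12 and 0.92 ± 0.14 (adjusted p = 0.044 for HSPH1). TPPP3, a microtubule-binding protein, changed by −1.14 ± 0.19. In all, 7 probe sets rose and 2 fell. Of 17 endoplasmic reticulum stress genes 1 rose (9 adjusted over the list alone; camera adjusted p = 6.6e-07, adjusted p = 0.632 with an estimated correlation). Of 18 smooth muscle markers 0 were called over all probe sets by limma, and 18 were lower adjusted over the list alone, with a median of −1.10 (camera adjusted p = 3.5e-13, adjusted p = 0.632 with an estimated correlation). At an unadjusted p under 0.05 there were 2661 probe sets. No call of a gene named here held without each array in turn, and HSPH1 ranged from 1.25 to 1.71. The count was 209 and 184 without non-infected replicate 2 and 1 dpi replicate 3, 1 without non-infected replicate 4 or 1 dpi replicate 2, and 0 without non-infected replicates 1 or 3 or 1 dpi replicates 1 or 4 (2030, 1715, 2014 and 2190 at an unadjusted p under 0.05, by limma). The endoplasmic reticulum stress count was 6 without non-infected replicate 2 and 0 without any other array except 1 dpi replicate 3 (9 or 10 at an unadjusted p under 0.05, by limma). The smooth muscle count of 18 became 0 without non-infected replicate 2 or 1 dpi replicate 1, 2 or 4, while camera passed each time.

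In colon at 2 dpi 5 of 18 smooth muscle markers fell, 4 of 26 fibroblast and matrix genes did, and a few inflammatory genes rose. The cardiac and enteric actins ACTC1 and ACTG2 changed by −5.85 ± 0.94 (adjusted p = 0.020) and −3.86 ± 0.81, and desmin, DES, by −3.07 ± 0.69. CXCL2 rose by 1.94 ± 0.37, LTB by 1.24 ± 0.18 (adjusted p = 0.015) and ICAM1 by 1.20. SLC5A1 rose by 1.21 ± 0.22. In all, 104 probe sets rose and 120 fell, of which 17 and 63 changed at least 2-fold. Of 18 smooth muscle markers 5 fell (17 adjusted over the list alone; camera adjusted p = 3.4e-16, adjusted p = 0.271 with an estimated correlation), with a median of −1.45. Of 26 fibroblast and matrix genes 4 fell (12 adjusted over the list alone; camera adjusted p = 1.0e-07, adjusted p = 0.304 with an estimated correlation), but the list did not pass fry (adjusted p = 0.0531) or the permutation test of its mean (exact p = 0.0857, adjusted 0.193). Of 13 cholesterol synthesis genes 1 fell, FDPS (−0.89), and 9 did adjusted over the list alone (camera adjusted p = 5.0e-08, adjusted p = 0.304 with an estimated correlation). Of 6 B cell markers 1 rose, LTB, which is in the cytokine list too (3 adjusted over the list alone; camera adjusted p = 0.0023, adjusted p = 0.271 with an estimated correlation). By limma over all probe sets 0 smooth muscle markers fell without any 1 array other than non-infected replicate 4 (16 or 17 at an unadjusted p under 0.05). The fibroblast count was 0 without non-infected replicate 1, 2 or 3 or 2 dpi replicate 1 or 3 (12 to 14 at an unadjusted p under 0.05, by limma), and 1 without 2 dpi replicate 2 or 4. The call of FDPS was the only one in its list; that count was 2 without non-infected replicate 2 and 0 without any other array (9 or 10 at an unadjusted p under 0.05, by limma). The B cell count was 2 without 2 dpi replicate 4, and 0 without non-infected replicate 1 or 2 dpi replicate 1 or 3 (3 at an unadjusted p under 0.05 each, by limma). Camera passed these 4 lists each time. No named gene of this comparison stayed called without each array in turn, though ACTC1 ranged from −6.10 to −5.19 and LTB from 1.13 to 1.39. The count of 224 was 83, 140 and 44 without non-infected replicate 3 and 2 dpi replicates 2 and 4, 4 and 2 without 2 dpi replicates 1 and 3, and 0 without non-infected replicate 1 (3168 at an unadjusted p under 0.05, by limma). The RNA integrity score was 1.33 ± 0.269 (SD, n = 4) at 2 dpi and 1.03 ± 0.137 in non-infected colon (exact permutation p = 0.114, adjusted 0.441). With it as a covariate, added after seeing the data, limma called 0 probe sets (2986 at an unadjusted p under 0.05). The median size of the change of the 224 was then 0.775 in place of 0.830, with a median standard error of 0.192 in place of 0.173, and 224 kept their sign.

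In colon at 6 dpi 6 of 30 cytokines and 4 of 24 markers of T and NK cells rose, and 11 of 18 smooth muscle markers and 7 of 26 fibroblast and matrix genes fell. ARG1, an arginine-degrading enzyme of myeloid cells, rose by 3.44 ± 0.47 (adjusted p = 0.0061), S100A9 by 2.89 ± 0.53 and granulysin, GNLY, a lytic protein of T and NK cells, by 1.95 ± 0.27. ACTC1 changed by −5.54 ± 0.94, the matrix protein asporin, ASPN, by −3.50 ± 0.51 and STMN2, a neuronal microtubule regulator, by −3.25 ± 0.43 (adjusted p = 0.0061). In all, 288 probe sets rose and 478 fell, of which 48 and 257 changed at least 2-fold. Of 30 cytokines 6 rose (13 adjusted over the list alone; camera adjusted p = 1.1e-05, adjusted p = 0.345 with an estimated correlation), with CCL3L1 and CCL5, which attract monocytes and T cells, at 1.11 and 1.14. Of 24 T and NK cell markers 4 rose (7 adjusted over the list alone; camera adjusted p = 0.00012, adjusted p = 0.345 with an estimated correlation), with CD8A at 1.09. Of 18 smooth muscle markers 11 fell (16 adjusted over the list alone; camera adjusted p = 7.1e-15, adjusted p = 0.345 with an estimated correlation), and of 26 fibroblast and matrix genes 7 fell (15 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.1e-08, adjusted p = 0.345 with an estimated correlation). The mean of the fibroblast list did not pass the permutation test (exact p = 0.114, adjusted 0.206). Without non-infected replicate 1, 0 smooth muscle markers fell by limma (16 at an unadjusted p under 0.05); the count was 3 and 6 without non-infected replicates 2 and 3, and 4, 1, 3 and 6 without 6 dpi replicates 1 to 4. The fibroblast count was 1, 3 and 4 without non-infected replicates 1, 2 and 3 and 3 without 6 dpi replicate 2, and the cytokine count 1 without non-infected replicate 1 and 2, 1 and 3 without 6 dpi replicates 1, 2 and 3. The T and NK count was 1 without non-infected replicate 1, 2 or 3 or 6 dpi replicate 1 or 3, and 2 without non-infected replicate 4 or 6 dpi replicate 2. Adjusted over the list alone it was 11 without non-infected replicate 1 and 4 without non-infected replicate 2 or 4 or 6 dpi replicate 1 or 2. Camera passed these lists each time. SLC26A3 changed by −1.43 and ABCG2 by −1.59. Of 44 named genes 9 stayed called without any 1 array (ACTC1, ARG1, ASPN, CHI3L1, GNLY, LTB, LUM, PLEK and STMN2), and S100A9 was lost without non-infected replicate 1 (2.47). The count of 766 was 88, 430 and 478 without non-infected replicates 1, 2 and 3, and 402, 284 and 311 without 6 dpi replicates 1, 2 and 3.

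The smooth muscle score, the mean of the 18 markers, moved with infection in colon. It was 10.0 ± 0.507 (SD, n = 4) in non-infected pigs, 8.79 ± 1.14 at 1 dpi, 8.34 ± 0.131 at 2 dpi and 8.35 ± 0.201 at 6 dpi (exact permutation p = 0.114, 0.0286 and 0.0286, the last being the smallest possible, and 0.206, 0.0857 and 0.0857 adjusted over 9 comparisons). With the score as a covariate, added after seeing the data, limma called 4 probe sets at 1 dpi and 0 at 2 and 6 dpi (1551 and 1059 at an unadjusted p under 0.05). The median size of the change of the called probe sets went from 0.830 to 0.628 at 2 dpi, with the median standard error going from 0.173 to 0.235, and from 0.864 to 0.491 at 6 dpi, with 0.189 going to 0.240.

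**Figure D3:**
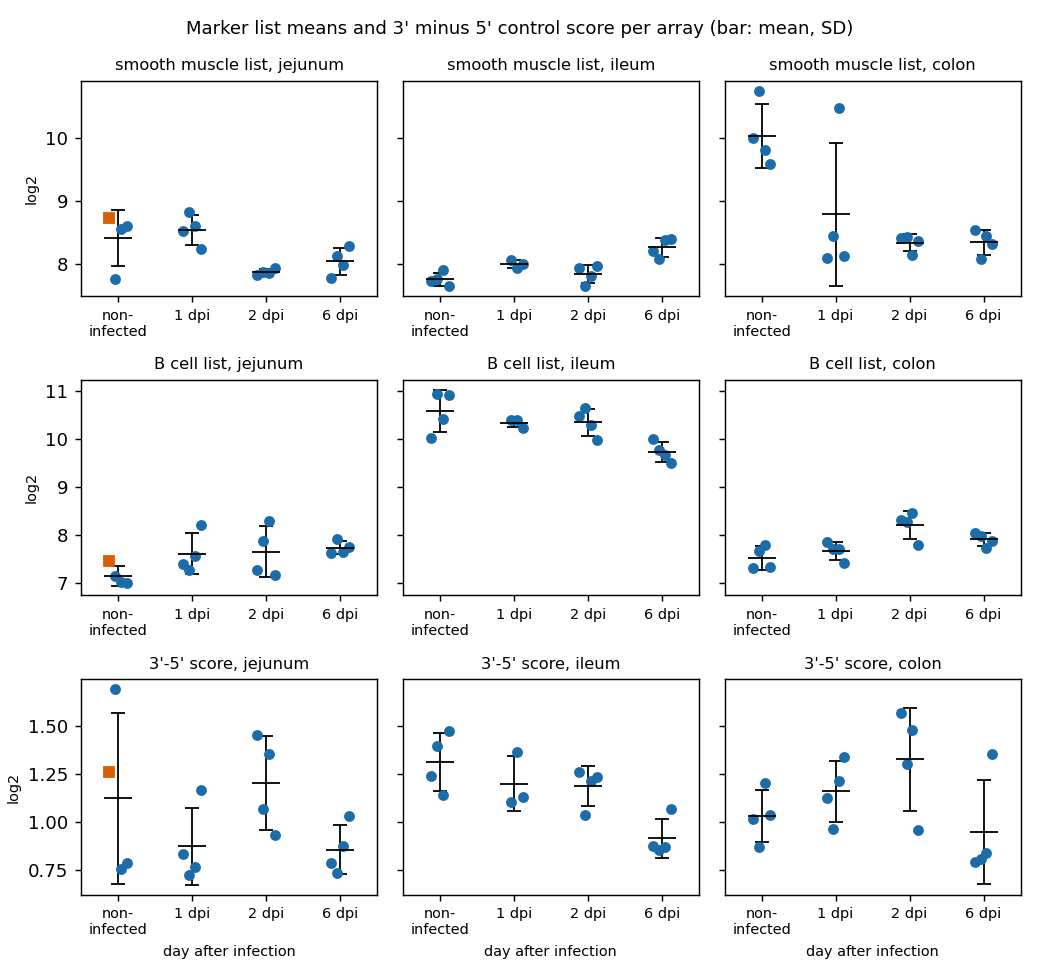
Mean log2 expression of the smooth muscle and B cell lists and the RNA integrity score (3′ minus 5′ control probe sets, log2) in each array by section and group, with group means and SD. The colon smooth muscle score was 10.0 in non-infected pigs and 8.35 at 6 dpi, and the ileum B cell score 10.6 and 9.74.

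The infected days were then compared with each other. In ileum 5766 probe sets differed among days, and 4940 between 6 and 2 dpi. DAO, a D-amino acid oxidase, went from −2.47 at 2 dpi to 1.36 at 6 dpi, a difference of 3.84 ± 0.27 (F adjusted p = 3.9e-06). FABP2, SLC5A1 and APOA1 were higher at 6 than at 2 dpi by 5.30 ± 0.55, 4.42 ± 0.42 and 5.11 ± 0.64, and S100A9 differed by −3.43 ± 0.92 (adjusted p = 0.016). Between 2 and 1 dpi 48 probe sets differed. In jejunum 1666 differed among days, with 743 higher and 142 lower at 2 than at 1 dpi, and 785 higher and 1362 lower at 6 than at 2 dpi. The interferon-stimulated genes USP18, XAF1, IFIT1 and MX1 were higher at 6 than at 2 dpi by 2.20 ± 0.26, 2.60 ± 0.33, 3.27 ± 0.41 and 2.45 ± 0.33, and in ileum IFIT3 was by 2.76 ± 0.34. ASNS was higher at 2 than at 1 dpi by 2.09 ± 0.26 and differed by −1.39 ± 0.26 between 6 and 2 dpi. In colon 263 probe sets differed, and GNLY was higher at 6 than at 1 dpi by 2.25 ± 0.27 (adjusted p = 0.0064) and ARG1 by 3.41 ± 0.47.

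The jejunum count among days was 1028 without 1 dpi replicate 3, 900, 996 and 713 without 2 dpi replicates 1, 2 and 3, and 848, 885 and 1095 without 6 dpi replicates 1, 3 and 4. The colon count was 72, 3, 6 and 20 without 1 dpi replicates 1 to 4, and 25, 70, 106 and 616 without 2 dpi replicates 1 to 4. Without colon 6 dpi replicate 1 it was 0 (4428 at an unadjusted p under 0.05, by limma), and without replicates 2, 3 and 4 it was 33, 50 and 857, so that GNLY and ARG1 lead a colon result that rests on its arrays.

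The last question was whether the change from non-infected pigs differed among the sections. It did for 95 probe sets at 1 dpi, 337 at 2 dpi and 2563 at 6 dpi, and with the pig as a random block for 365 at 1 dpi and 743 at 2 dpi (472 and 980 without the array labelled jejunum non-infected replicate 1), while the 6 dpi count stayed within 1.5 times. SLC5A1 was at −0.21 in jejunum, −4.51 in ileum and 1.21 in colon at 2 dpi (F adjusted p = 0.00017, 4.4e-05 with the block). FABP2 was at 0.98, −5.61 and 0.20 (F adjusted p = 0.027) and FABP6 at −5.93, −5.75 and 0.56 (F adjusted p = 0.0079). The jejunum value of FABP2 turned to −1.503 (not called) without the array labelled jejunum non-infected replicate 1, and those of SLC5A1 and FABP6 became −1.05 and −6.94. The F adjusted p was then 3.1e-06 for FABP2, 9.6e-07 for SLC5A1 and 0.00091 for FABP6, and FABP2 differed between ileum and jejunum by −4.11 ± 0.69. HP was at 2.85 in jejunum and −0.04 in ileum at 2 dpi (difference −2.89 ± 0.53). At 1 dpi CCL2 was at 1.10, 2.00 and −0.92 and SOD2 at 0.74, 1.97 and 0.15 in jejunum, ileum and colon (F adjusted p = 0.0046 for both). For S100A9 the test did not pass at 1 dpi (F adjusted p = 0.105) or 2 dpi (0.202). At 6 dpi ACTG2 was at −0.50, 1.58 and −4.04 (F adjusted p = 0.00035), ASPN at 0.50, 0.34 and −3.50 (F adjusted p = 0.00012) and CD79B at 0.21, −1.37 and 0.31 (F adjusted p = 0.0126). Without that array the jejunum values were 2.87 for HP, 1.22 for CCL2, 0.80 for SOD2, −0.47 for ACTG2, 0.67 for ASPN and 0.39 for CD79B, and these tests passed too.

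Single arrays moved the tests among sections. At 1 dpi the count of 95 became 154 without jejunum non-infected replicate 1, 155, 26 and 27 without jejunum 1 dpi replicates 1, 2 and 3, 17 and 46 without ileum non-infected replicates 2 and 4, 44 and 14 without ileum 1 dpi replicates 2 and 4, 56 and 22 without colon non-infected replicates 1 and 3, and 40, 33, 326 and 19 without colon 1 dpi replicates 1 to 4. At 2 dpi the count of 337 became 528 and 608 without jejunum non-infected replicates 1 and 2, 569 without jejunum 2 dpi replicate 4, 179 and 138 without ileum non-infected replicates 2 and 4, and 152, 124 and 138 without ileum 2 dpi replicates 1, 2 and 4. It was 157 without colon non-infected replicate 2, and 216, 221 and 217 without colon 2 dpi replicates 1, 2 and 4. At 6 dpi the count of 2563 became 1698 without ileum non-infected replicate 2.

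Over the 27 lists, camera passed 20, 15 and 13 at 1, 2 and 6 dpi in jejunum, 14, 19 and 14 in ileum, and 5, 11 and 13 in colon. With an estimated correlation 0 passed in any of the 9 comparisons (6, 3 and 3 in jejunum, 5, 4 and 2 in ileum, and 2, 3 and 3 in colon at an unadjusted p under 0.05). By fry, which asks whether the genes of a list move one way on balance, 0, 10 and 0 passed in jejunum, 9, 12 and 11 in ileum, and 0, 3 and 9 in colon. The camera calls of 7, 12 and 9 lists in jejunum at 1, 2 and 6 dpi, 13, 13 and 9 in ileum, and 4, 7 and 5 in colon held without any 1 array. The list of erythroid genes passed camera in none of the comparisons. With the arrays of a section regrouped at random, camera passed up to 43, 49 and 45 lists and days in jejunum, ileum and colon. The real groups gave 48, 47 and 29, so a camera call of 1 list is weak support by itself.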

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

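The tests of a swap, of colon RNA and of absorptive cell loss for the array labelled jejunum non-infected replicate 1 were chosen only after the result was seen. So were those of less muscle layer and of contractile genes alone in colon, and of RNA integrity and B cell share in ileum at 6 dpi. The joint normalization of jejunum and colon and the splits of whole pigs were as well. The prediction of the RNA integrity test in colon was written before its result, but its covariate was added after the data were seen. The other counts of splits were chosen before.

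The array labelled jejunum non-infected replicate 1 lies near colon, and a swap with a colon array of this series is excluded, because the highest FABP2 level among the 16 colon arrays was 3.41 log2, far under the lowest of the other 15 jejunum arrays (9.96). A loss of absorptive cells in that pig's jejunum is argued against by 30 genes at least 8-fold higher in colon than in jejunum, whose median position in this array was 0.975 on a scale from 0 (jejunum) to 1 (colon), with quartiles of 0.848 and 1.09. The sections appear to have been normalised apart, but with both normalised together the colon and jejunum FABP2 bounds were 3.29 and 10.01 and the median position 0.985 over 28 genes. Over probe sets that vary like alleles its correlation with the pig of its own number was 0.958, and 0.700 with the next best pig. Colon RNA of the same pig under a jejunum label is therefore a candidate explanation that stays open, and no biological explanation from the design was tested.

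Smooth muscle genes were lower in infected colon. RNA integrity is argued against at 6 dpi, since the median change of the list was −1.51 (standard error of the mean over genes 0.264) with the 3′ minus 5′ score as a covariate. The score itself differed little from non-infected colon on that day (−0.084, exact permutation p = 0.571). At 1 and 2 dpi RNA integrity was not tested for this list and stays open. Lower expression of contractile genes alone is argued against by 10 genes of enteric neurons and glia, whose median change was −1.07 with 9 of them lower. The standard error of their mean over genes, not pigs, was 0.307. The fall was uneven. UCHL1 and GAP43 were at −2.88 and −2.39, while S100B (−0.67) and GPM6B (−0.42) fell less and SOX10 (−0.07) and NPY (0.07) were near 0. S100B and SOX10 mark glia, so the result rests mainly on the neuron genes. Less muscle layer in the infected samples may explain it but stays open, because within 1 dpi the score spanned 2.39 log2, more than the 1.70 between non-infected pigs and pigs at 2 and 6 dpi, and only 0.351 without replicate 3. A loss of muscle and nerve tissue through the infection predicts the same values and stays open, untested.

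The ileum at 6 dpi had many small changes. A lower share of B cells alone is argued against, because the medians of the macrophage list (0.982) and of the T and NK cell list (0.191) differed by 0.791, where markers of the other cell types would rise alike. The standard error over genes, that of a difference of means, was 0.169. Without 6 dpi replicate 2 the medians differed by 0.412 (0.139). These errors are over genes, which are not independent, and do not measure the spread between pigs. A shift of several cell types together was not tested. RNA integrity may contribute: across probe sets, which are not independent, the slope on the 3′ minus 5′ score among 15 jejunum arrays, fitted without the array labelled jejunum non-infected replicate 1, correlated with the ileum change at 6 dpi at r = −0.493 (−0.464 without non-infected replicate 2 as well), against 0.0406 at 1 dpi and −0.173 at 2 dpi. Those slopes gave the called direction for 3817 (80.9%) of the 4719 probe sets, but a median predicted change of 0.135 where 0.608 was observed. An effect of the day of infection stays open, as the score is partly confounded with it.

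The change from non-infected pigs differed among the sections for 95 probe sets at 1 dpi, 337 at 2 dpi and 2563 at 6 dpi, by an interaction test. At 1 dpi the smallest adjusted p was 0.00464 for SULT2A1, SLC5A1, CCL2, HSPB7, SOD2 and SLC25A38 alike. At 2 dpi it was 0.000168 for SLC5A1, 0.000887 for IL27RA, 0.00157 for RTN1, 0.00320 for HP, 0.00416 for SFTPD and 0.00636 for PDLIM3. At 6 dpi it was 0.000121 for KDM2A and ASPN, 0.000164 for PABPN1, 0.000171 for FAM198B, 0.000206 for CAV1 and 0.000232 for PDLIM3.

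In 24 of 253 sets of 4 arrays, 1 array lay far from the other 3, where about 1 in 20 would by chance (12.65 sets). The array labelled jejunum non-infected replicate 1 stood apart in FABP2 (3.66), MUC4 (8.28) and the enterocyte list (7.23), and jejunum non-infected replicate 2 in JCHAIN (7.85) and STMN2 (6.17). Other jejunum arrays were 1 dpi replicate 4 in the SD over probe sets (2.17), 1 dpi replicate 2 in the neutrophil list (6.06), 2 dpi replicate 3 in ACTG2 (8.61), 2 dpi replicate 4 in DES (7.40), and 6 dpi replicate 2 in S100A9 (5.67) and the neutrophil list (6.49). In ileum they were 2 dpi replicate 4 in the cell cycle list (9.49), 6 dpi replicate 1 in the goblet cell list (8.84), 6 dpi replicate 2 in the neutrophil list (7.30) and the T and NK cell list (7.42), and 6 dpi replicate 4 in the 3′ minus 5′ score (1.07). In colon they were non-infected replicate 2 in MUC4 (9.40) and ACTC1 (11.8), 1 dpi replicate 1 in MUC4 (10.4), 1 dpi replicate 3 in the smooth muscle list (10.5), 2 dpi replicate 2 in S100A9 (6.501) and the cell cycle list (8.45), and 6 dpi replicate 4 in the 3′ minus 5′ score (1.36) and the fibroblast list (8.57).

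Each count was compared with that of other splits of the same arrays, 35 for a comparison with non-infected pigs and 100 otherwise. Chance was taken as excluded where a share under 0.05 of the splits gave as large a count, with no adjustment over the results. With 35 splits, 1 is the smallest number possible. By this rule chance was excluded (1 split as large, the real one) in jejunum at 2 dpi (680 probe sets, highest other split 206) and 6 dpi (18, other 16), in ileum at 1, 2 and 6 dpi (1428, 1232 and 4719, others 445, 1 and 2023) and in colon at 2 and 6 dpi (224 and 766, others 176 and 4). The margin was narrow in jejunum at 6 dpi and in colon at 2 dpi. Chance was also excluded for the differences among days in jejunum, ileum and colon (1666, 5766 and 263, others 1066, 3694 and 6). The counts of lists in jejunum (48 with 1, other 43) and ileum (47 with 2, other 49) pass the rule too. The largest of the other splits passed 43 and 49 lists and days there. A single list past camera at the preset correlation therefore does not exclude chance. Among sections, 4 splits were as large at 1 dpi (95, other 374) and 1 at 6 dpi (2563, other 2243). Both pass the rule, but no conclusion is drawn from these splits, for the reason given below. By splits drawn within each section, chance was not excluded in jejunum at 1 dpi (1 probe set with 4 splits as large, other 3), in colon at 1 dpi (9 with 2, other 321), among sections at 2 dpi (337 with 7, other 634) or for the lists in colon (29 with 27, other 45). The colon split with 321 set non-infected replicates 1, 2 and 3 with 1 dpi replicate 3 against the rest, and these 4 have the highest smooth muscle scores of the 8 (9.82 to 10.8), so that it points to a structure of the samples, although non-infected replicate 4 (9.59) lies close to them and on the other side. The split with 374 among sections at 1 dpi also calls several times the real count and points to a structure too; it was not traced to a property of the arrays. These splits among sections did not keep the arrays of a pig together, so they cannot decide whether chance is excluded there. With the pig as a random block and whole pigs moved, the real split alone was as large of 35 at 1, 2 and 6 dpi (365, 743 and 3633, others 233, 258 and 5). Moving whole pigs also breaks any infection effect that the sections share, which can widen the spread within groups and lower the other counts. The correlation within pigs was estimated once, on the real groups. These splits therefore set the real grouping against no infection effect in any section, and do not decide whether the sections differ by chance. The real split alone was as large too without the array labelled jejunum non-infected replicate 1 (472, 980 and 3776, others 287, 352 and 39). The split with 233 moved the same pigs as the colon split with 321.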

How the results depend on the processing

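The fits with the 3′ minus 5′ score or the smooth muscle score as a covariate, without jejunum non-infected replicates 1 and 2 together, and with the pig as a block but without the array labelled jejunum non-infected replicate 1 were chosen only after the result was seen. The cause was not tested for any value below unless it is named. The comparison of sections in non-infected pigs, and its version with a block, was not run because the sections appear to have been normalised apart.

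Leaving out each array in turn gave 1 to 6, 154 to 1028 and 3 to 109 probe sets in jejunum at 1, 2 and 6 dpi, 427 to 1485, 595 to 1257 and 2977 to 6052 in ileum, and 0 to 209, 0 to 227 and 88 to 841 in colon. It gave 713 to 2093, 4123 to 6134 and 0 to 857 for days in jejunum, ileum and colon, 14 to 326, 124 to 608 and 1698 to 3118 among sections at 1, 2 and 6 dpi, and 41 to 52, 44 to 48 and 21 to 34 lists.

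Array weights gave 75, 3368 and 861 in jejunum, 51 and 508 in colon at 1 and 2 dpi, 7161 and 2569 for days in jejunum and colon, and 954, 1651 and 4618 among sections. A fit of all arrays gave 142, 2461 and 717 in jejunum, 817 and 689 in ileum at 1 and 2 dpi, and 90 and 606 in colon at 1 and 2 dpi. With only the 2 groups compared the counts were 0, 107 and 2 in jejunum, 809 in ileum at 1 dpi, and 0 and 452 in colon at 1 and 6 dpi; limma had 1552 and 2505 at an unadjusted p under 0.05 for the zeros. Quantile normalization gave 11 in jejunum at 6 dpi, and 5 and 438 in colon at 1 and 2 dpi; centring on the median gave 2 in jejunum at 1 dpi.

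The replicate number as a fixed block, which within a section joins different pigs, gave 301 and 6 in jejunum at 2 and 6 dpi, 0 and 144 in colon at 1 and 2 dpi (2360 at an unadjusted p under 0.05 for the zero, by limma), and 821 and 56 for days in jejunum and colon. In ileum it gave 1622, 1660 and 5962, and 7109 for days, all higher than without it. Deviations of same-numbered ileum arrays correlated at 0.153 to 0.295 for number 1, 0.0184 to 0.288 for number 2, −0.361 to 0.232 for number 3 and 0.146 to 0.274 for number 4. Each number in jejunum and colon had a negative pair. In ileum the pairs of numbers 1, 2 and 4 were all positive. A shared effect that follows the number in ileum is therefore not excluded, and it was not tested. Among sections the pig as a random block gave 365 and 743 at 1 and 2 dpi, and 472 and 980 without the array labelled jejunum non-infected replicate 1. Without jejunum non-infected replicates 1 and 2 the counts were 5 at 6 dpi and 2753 for days. Leaving out dim probe sets gave 52 among sections at 1 dpi.

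Asking for 2-fold as well can only lower a count: 271 in jejunum at 2 dpi, 439, 390 and 681 in ileum, 4, 80 and 305 in colon, 592, 939 and 46 for days, and 59 and 1197 among sections at 1 and 6 dpi. Testing 1 probe set per gene tests fewer features: 2, 318 and 7 in jejunum, 689, 621 and 1508 in ileum, 386 in colon at 6 dpi, 507, 1984 and 151 for days, and 189 and 887 among sections at 2 and 6 dpi.

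The 3′ minus 5′ score as a covariate gave 513 and 0 in ileum at 2 and 6 dpi, 0 in colon at 1 and 2 dpi, and 668, 1760 and 6 for days. The zeros had 3230, 2819 and 2986 at an unadjusted p under 0.05, by limma. In colon the changes stayed about as large (median 0.919 to 0.910 at 1 dpi and 0.830 to 0.775 at 2 dpi, with 9 and 224 signs kept), while their median standard errors went from 0.145 to 0.153 and from 0.173 to 0.192; in ileum at 6 dpi the change went from 0.608 to 0.501 and the error from 0.146 to 0.240. The smooth muscle score gave 4, 0 and 0 in colon (1551 and 1059 for the zeros), 60 for days and 16 lists. Of 29 lists in colon, 47 in ileum and 48 in jejunum that passed camera, 0 passed with an estimated correlation. By fry 10 passed in jejunum and 12 in colon, and without dim genes 30 in ileum.

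Of 355 calls of named genes, 1986 of 2770 values with 1 array left out stayed called, 784 did not and 0 turned. Averaging all probe sets of a gene kept 324, lost 30 and turned 1, NDUFA1 in jejunum at 2 dpi, to 1.14. Quantile normalization kept 346, trend and robust 337, array weights 336, the fixed block 311, all arrays 280, the 2 groups alone 244 and the 3′ minus 5′ covariate 184, and the smooth muscle covariate 1 of 76. Without jejunum non-infected replicates 1 and 2, 21 of 49 jejunum calls were kept and 28 lost. Dim probe sets could be called changed less easily, as background limits their signal. Where they were left out, 289 of the 355 calls could be tested and 289 held. The adjustment was then over fewer probe sets, so this setting is a weak check of those calls. The other calls were of dim probe sets, which this filter removed.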

Other observations

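The values in this part were picked out after they were seen, and no test was added for them. Genes for iron and metal handling, which move metals that hosts and bacteria compete for, were a further group with calls. In ileum at 1 dpi 5 of 19 rose (7 adjusted over the list alone; camera adjusted p = 0.0034, adjusted p = 0.206 with an estimated correlation). In jejunum at 2 dpi 4 of 19 rose (8 adjusted over the list alone; camera adjusted p = 0.0085, adjusted p = 0.297 with an estimated correlation), among them SLC11A1, the phagosomal metal pump that bears on resistance to Salmonella, at 2.45 ± 0.47, a call lost without 2 dpi replicate 3 (2.105). In ileum at 2 dpi SLC11A1 was at 2.12, a call lost without non-infected replicate 2 (1.88) or 2 dpi replicate 2 (1.89) or 4 (2.16). In ileum at 6 dpi the transferrin receptor TFRC rose by 1.38 and the metallothionein MT1A by 1.37.

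In jejunum at 2 dpi 0 of 29 enterocyte genes were called by limma, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.902). Without the array labelled jejunum non-infected replicate 1 their median change was −0.82 and 4 fell adjusted over the list alone (camera adjusted p = 5.7e-07, adjusted p = 0.367 with an estimated correlation).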
